A study of Mus musculus with 2 samples.

How the data were processed

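Trimethylation of lysine 9 of histone H3 (H3K9me3) was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in hindbrain of mouse embryos of strain B6NCrl at embryonic day 11.5. Per the labels, replicate 1 pooled hindbrains of 109 embryos and replicate 2 those of 88 embryos, with both sexes mixed in each pool. The replicates are therefore separate biological pools. Per the labels, replicate 1 also combined 2 technical replicates, sequenced on a pair of Illumina instrument models, and replicate 2 had 1. Only 1 group was profiled, so no condition could be compared with another. The comparisons made were between the replicates, and between the peaks and random positions or genes.

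The authors deposited 4 peak lists in narrowPeak format on the mm10 build. Per the file headers and the text files deposited beside them, each replicate's list was made from the filtered alignments of that replicate and a control. Per the same text files, the list of the pooled reads came from both replicates together, and the replicated list was derived from the pooled list and both replicates' lists. Each deposited peak carries a linear ratio, the fold enrichment of ChIP over control as the authors' caller gave it. Each deposited peak also carries a −log10 p and a −log10 q, with a −log10 q of 0 standing for a q of 1. The aligner, the peak caller, its threshold and the rule that made a peak replicated are not given in the sources used here. Fold, p and q are the authors' values for each peak and were used only to describe, rank or filter peaks within a list. The lists are permissive. No peak had a −log10 p under 2.05, and 36.4% of the replicated peaks, 39.1% of replicate 1's and 27.9% of replicate 2's had a q under 0.05.

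The files hold no read counts, so the depth of each replicate is unknown. No interval that needs depth was computed. Intervals on shares of genes or peaks are exact Clopper-Pearson 95% intervals, and those on densities are exact Poisson 95% intervals. Both cover counting error only. For a count of 0, the limit given in the text is 3 genes as a share of the list, and the exact upper bound, drawn in the figure of gene lists, is higher. Fold values came in steps: 5 values were shared by 46.0% of replicate 1's peaks and by 49.9% of replicate 2's, so ranks by fold hold many ties.

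Positions were analysed on chromosomes 1 to 19, X and Y of GRCm38.p6, the assembly that mm10 names, with gene models of GENCODE release M21. Repeats are the soft-masked bases of that assembly's RefSeq sequence. Peaks on unplaced or unlocalized scaffolds were counted separately. Overlap meant 1 bp or more. Overlaps, random placements and tests were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. The overlap counts between replicates were checked with bedtools 2.31.1, which gave the same 4283 and 4360 peaks. Uniqueness of sequence was measured as the share of 31-mers that occur once in the assembly.

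Overlap between replicates was set against 1000 random placements of the other replicate's peaks on their own chromosomes, with a one-sided permutation test whose smallest p is 0.001. Genomic features were assigned by the peak summit, in the order within 1 kb of a transcription start site (TSS), exon, intron and outside genes. Features and repeat-masked shares were set against 1000 placements outside assembly gaps, with two-sided permutation tests whose smallest p is 0.002. The share of genes with a peak was measured in 18 gene lists and set against 10000 random lists of protein-coding genes matched on length in 20 bins. That permutation test was two-sided, its smallest p is 0.0002, and p-values were adjusted by Benjamini-Hochberg over the 18 lists. All symbols of the lists were found in the annotation. The zinc finger list was taken by symbol (Zfp, Znf, Zkscan and Zscan with a number). Peaks on the last exon and at the TSS of zinc finger genes were compared by an exact McNemar test. Peaks were also counted in 1 Mb windows.

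Genes were named by a rule: in each list, genes were ranked by the highest fold of a replicated peak that also overlapped a peak in each replicate's own list. The first 6 were taken from the zinc finger, imprinted and germline lists and the first 2 from each other list. The 10 replicated peaks of highest fold on the chromosomes were named with the gene they overlap or the nearest TSS, and so were up to 3 genes in each of the 3 densest windows. The groups, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. Alternatives covered overlap of 50% of the peak's length, stricter thresholds, equal list lengths, the pooled list, each replicate's own list, other gene windows and rotation of the peaks along chromosomes. Those named as chosen after seeing the data are a gene's own first exon, a q under 0.05 and placements in unique sequence. Values given as without replicate 1 come from the 4452 peaks of highest −log10 p in replicate 2's own list. Those without replicate 2 come from the same number of replicate 1's peaks. Peaks of these shortened lists need no partner in the other replicate, so they are not the replicated list with a replicate removed.

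The measurements were tested on simulated data. Peaks planted in 40 zinc finger genes were recovered as an enriched list in 20 of 20 simulations of the 4216 chromosomal peaks. In the same simulations, 22 of 340 tests of the other lists were also called. Where peaks were scattered at random over the whole genome, 16 of 360 list tests passed an adjusted p of 0.05. With no true excess, the adjustment is meant to hold the chance of any call in a simulation to 0.05. The 16 calls are a total over 20 simulations, and several can fall in the same simulation, so they cannot be set against that chance directly. These simulations also scattered peaks singly, so their rate of calls does not carry over to the clustered real peaks. An adjusted p near 0.05 is therefore taken as weaker evidence than it states. Where peaks were scattered within their own chromosomes, 33 of 360 passed. Of these, 15 were for the protocadherin list and 8 for the vomeronasal receptor list. The zinc finger, olfactory receptor, ribosomal protein and cytochrome P450 lists were each called in 2 of 20 simulations. Protocadherin and vomeronasal receptor genes lie side by side and on chromosomes rich in peaks, so random gene lists understate chance most for them. The rotation of all peaks along their chromosomes keeps that clustering, and its p is given beside the results of clustered lists. Simulated replicates that shared 30% of their peaks gave a mean overlap of 30.1%.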

Results

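H3K9me3, a histone modification found on silent chromatin, was mapped in the mouse hindbrain at embryonic day 11.5, when the tissue holds mostly neural progenitors and young neurons. The group comprised 2 biological replicates, pools of 109 embryos (replicate 1) and 88 embryos (replicate 2). Replicate 1 gave 13794 peaks and replicate 2 gave 23450. The pooled reads of both gave 7271, of which 4452 formed the replicated list used for most comparisons. Replicated peaks had a median length of 300.0 bp and a median fold enrichment over control of 3.32, with quartiles of 2.97 and 3.65. On the chromosomes lay 4216 of them. All coordinates are on mm10.

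The first question was whether both pools of hindbrain carried the mark at the same places. Of replicate 1's 13517 chromosomal peaks, 31.7% (95% interval 30.9 to 32.5%) were overlapped by a replicate 2 peak. Of replicate 2's 23161, 18.8% (18.3 to 19.3%) were overlapped by a replicate 1 peak. Random placements gave 0.611% and 0.357%, so the overlap was 51.9 and 52.8 times theirs (permutation p = 0.001 for each, one-sided, the smallest that 1000 placements can give). Those placements scatter peaks singly and do not keep their clustering. The ratios therefore count shared regions of dense peaks as well as shared positions, and a null that keeps the clustering was not run for this overlap. Most peaks of each list had no partner in the other. The overlap was highest among strong peaks, at 67.1% in the tenth of replicate 1's list with the highest −log10 p and 19.5% in the tenth with the lowest. With the same number of top peaks taken from both lists, the shares were 24.1% of replicate 1's and 23.97% of replicate 2's peaks. Among the replicated peaks, 86.2% overlapped a peak in both replicates' own lists. Across those 3838 peaks the folds of both replicates were weakly correlated (Spearman's rho 0.246, 95% bootstrap interval 0.212 to 0.276, and Pearson's r 0.33 on log2 values). These correlations are across peaks, which are not independent replicates. The median fold was 3.67 in replicate 1 and 3.46 in replicate 2.

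**Figure D1:**
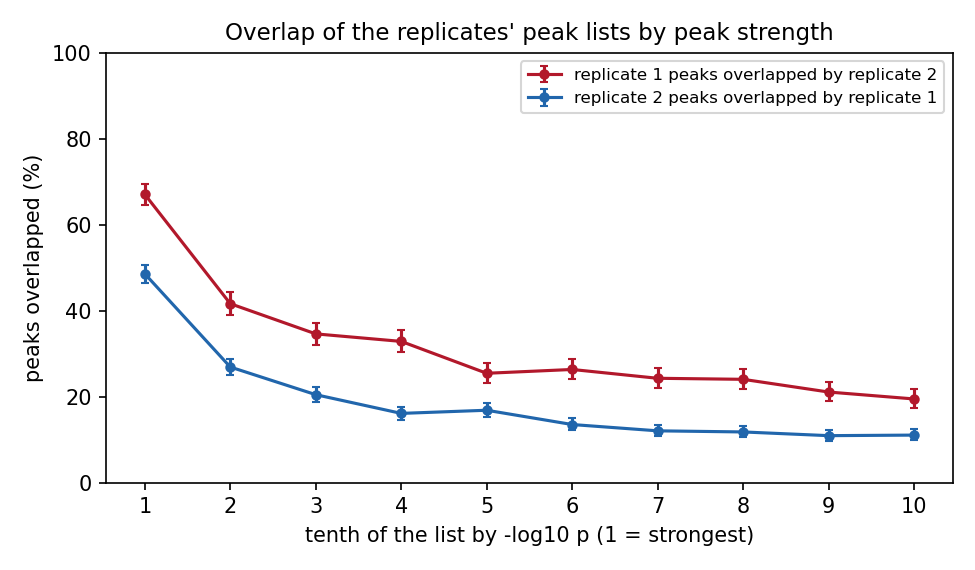
Share of each replicate's peaks overlapped by the other replicate's peaks (%, vertical axis) in 10 equal groups of the list ordered by −log10 p (horizontal axis, 1 is the strongest). Bars are exact 95% intervals. The share falls from 67.1% to 19.5% in replicate 1 and from 48.6% to 11.1% in replicate 2.

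The replicated peaks were then placed on genes. Protein-coding genes carried them rarely: 891 of 21938 (4.06%) overlapped one. By summit, 495 peaks (11.7%) lay within 1 kb of a TSS, 414 (9.82%) in other exons, 1323 (31.4%) in introns and 1984 (47.1%) outside genes. Exons held 2.73 times and TSS windows 1.73 times as many as random placements did, which gave 3.60% and 6.77%. Introns held fewer than the 40.02% of random placements (permutation tests, adjusted p = 0.0027 for each of these 3 classes). The placements scatter peaks singly, so these tests treat clustered peaks as independent. They also fall in non-unique sequence more often than peaks do, and the ratios were not corrected for that. The share outside genes lay slightly below the 49.6% of random placements (permutation test, adjusted p = 0.0040), and that difference was lost with the pooled list (49.1%, permutation test, adjusted p = 0.43) and without replicate 1 (49.6%, permutation test, adjusted p = 0.74). In replicate 2's whole list it was reversed (51.9% against 49.9% of random placements, permutation test, adjusted p = 0.0020), and in replicate 1's it was 50.7% against 49.9% (permutation test, adjusted p = 0.066). Replicate 1's whole list placed 6.72% and replicate 2's 5.57% of summits in exons, 1.91 and 1.60 times their random placements. On average 21.4% of a replicated peak's bases were repeat-masked (95% bootstrap interval 20.7 to 22.0%), below the 34.0% of random placements (two-sided permutation p = 0.002, the smallest these placements can give). Among peaks and placements with at least 90% unique 31-mers, a comparison chosen after seeing the data, both averaged 18.8%. The equal averages came from a mix of peaks on and off exons that differed in its shares. Off exons, peaks in such sequence averaged 20.6% (95% bootstrap interval 19.9 to 21.3%) and placements 19.4%, while on exons the averages were 10.99% (10.05 to 12.1%) and 13.7%, with 715 of 3685 peaks and 1556 of 14534 placements on exons.

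Clustered protocadherins, cell-surface adhesion proteins that give neurons individual identities, were the most heavily marked gene list. Of 57 genes, 46 (80.7%, 95% interval 68.1 to 89.95%) overlapped a replicated peak, against 6.54% of length-matched genes (permutation test, adjusted p = 0.00072 over 18 lists, and 0.012 with rotation of the peaks). Alpha and gamma genes are nested and share downstream exons, so these genes carried 135 distinct peaks rather than independent sets. A gene's own first exon, which encodes the part unique to each isoform, held a peak in 11 of 14 alpha, 15 of 22 beta and 18 of 21 gamma genes. The alpha genes spanned chromosome 18 from 36930184 to 37187661 with 34 peaks. The beta genes spanned 37264938 to 37524479 with 45 peaks, and the gamma genes 37661793 to 37841873 with 76. First exons covered 30.6% of the gamma span and were overlapped by 60.5% of its peaks. The strongest peak of the locus, at 37720936 to 37722030, had a fold of 5.67 and lay inside the bodies of Pcdhga1 and Pcdhga2, on exon sequence of other genes of the cluster. Its folds were 5.80 in replicate 1 and 6.04 in replicate 2.

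**Figure D2:**
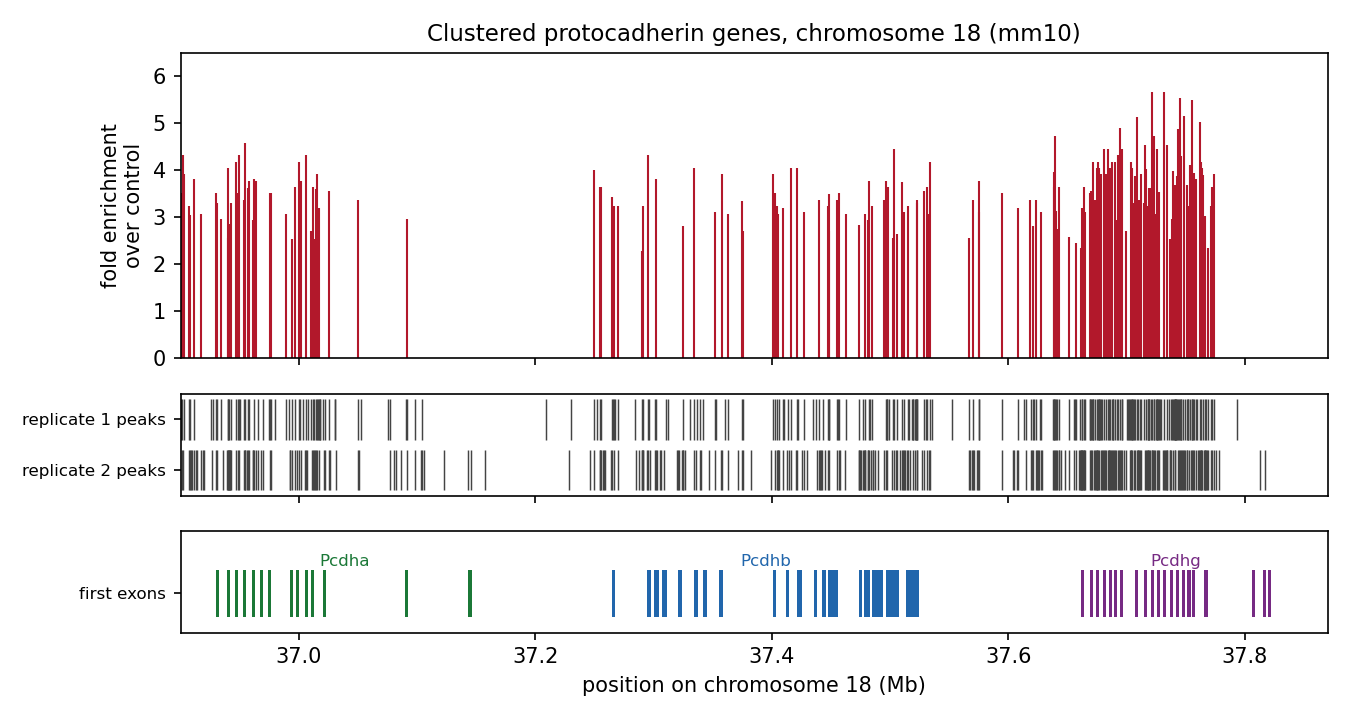
The protocadherin clusters on chromosome 18 (position in Mb, horizontal axis). Top, fold enrichment over control of each replicated peak, drawn at its midpoint. Middle, peaks of each replicate's own list. Bottom, first exons of the Pcdha, Pcdhb and Pcdhg genes. The gamma genes hold 76 replicated peaks and the highest fold, 5.67.

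Zinc finger genes, mostly transcription factors of the Krüppel type, were the list with the most marked members. Of 418 genes, 88 (21.1%, 95% interval 17.2 to 25.3%) overlapped a replicated peak, 7.19 times the 2.93% of length-matched genes (permutation test, adjusted p = 0.00072, and 0.012 with rotation of the peaks). In replicate 1's own list the share was 30.6% and in replicate 2's 38.5%, against 11.7% and 18.6% of all coding genes. Those coding genes are not matched on length, and the whole lists were not set against length-matched genes. A peak covered part of the last exon, which usually encodes the zinc finger array, in 64 of the 88 genes, and lay within 1 kb of the TSS of the longest coding transcript in 5. Counting every annotated TSS of a gene, as for the imprinted genes below, 19 of the 88 had a peak within 1 kb. Of the genes with a peak on only the last exon or only the TSS of the longest coding transcript, 61 had it on the last exon and 2 at the TSS (exact McNemar p = 4.4e-16). The McNemar test treats genes as independent, although some are neighbours, such as the 9 between 12 and 13 Mb of chromosome 7. Per kb of sequence, last exons had 0.0537 and TSS windows 0.0060 marked genes. Restricted to within 1 kb of the TSS, the list lost its call (1.20% against 0.466% of matched genes, a ratio of 2.57, permutation test, adjusted p = 0.41), with 5 marked genes left.

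Zfp810 had the strongest zinc finger peak, on chromosome 9 from 22276916 to 22277914 in the 3′ UTR of its last exon, with a fold of 7.02 from the pooled reads, 6.06 in replicate 1 and 8.05 in replicate 2. In Zfp180 a peak of 3644 bp on chromosome 7 (24103922 to 24107565, fold 6.01) included 1718 coding bases of the last exon and 1443 of its 3′ UTR. Zfp606 on chromosome 7 (12493153 to 12494365) and Zfp68 on chromosome 5 (138605706 to 138607283) each had a fold of 5.94, with 1183 and 1042 coding bases inside the peak. Zfp981 on chromosome 4 (146520119 to 146520588) and Zfp945 on chromosome 17 (22853293 to 22853979) had their strongest peaks in introns, with folds of 6.39 and 5.94. Zfp981 held 16 replicated peaks in all. Some zinc finger genes have near-identical copies, so the position of reads among copies is uncertain.

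Imprinted genes, expressed from only one parental allele, were also marked more often than matched genes. Of 44 genes, 19 (43.2%, 95% interval 28.3 to 59.0%) overlapped a replicated peak against 5.47% (permutation test, adjusted p = 0.00072, and 0.012 with rotation of the peaks). Neighbouring genes shared peaks, and the 19 genes amounted to 15 separate loci with 31 peaks. In 12 of the 19 a peak lay within 1 kb of an annotated TSS. Impact had the highest fold (4.46, chromosome 18 from 12972784 to 12973196, in an intron 1.10 kb from the TSS). Mest followed with 4.21 (chromosome 6 from 30738024 to 30738300, in the first exon 0.092 kb from its TSS), and its folds were 5.22 in replicate 1 and 3.14 in replicate 2. Gnas and its antisense transcript Nespas shared a peak of fold 3.78 on chromosome 2 (174285343 to 174285617). Grb10, a growth-restraining adaptor, had a peak of the same fold on chromosome 11 (12026513 to 12027155), and Zdbf2 one of 3.69 in an intron on chromosome 1 (63285146 to 63285376). With replicated peaks of q under 0.05 only, chosen after seeing the data, 6 of the 44 imprinted genes kept a peak (13.6%, permutation test, adjusted p = 0.0018).

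Germline genes, which act in egg and sperm precursors and are silent in most body cells, were marked in 6 of 49 (12.2%, 95% interval 4.63 to 24.8%) against 3.95% of matched genes. This missed the threshold (permutation test, adjusted p = 0.055), but passed with rotation of the peaks (permutation test, adjusted p = 0.036) and within 1 kb of the TSS (6.12%, permutation test, adjusted p = 0.040). It also missed with the pooled list (2.09 times matched genes, permutation test, adjusted p = 0.27) and with 5 kb either side (2.49 times, permutation test, adjusted p = 0.13). Without replicate 1 the ratio turned to 0.911, with 2 marked genes, and without replicate 2 it was 1.35, with 3, in place of 3.10. All 6 had a single peak. The RNA helicase gene Ddx4 had its peak over the TSS and 5′ UTR on chromosome 13 (112652039 to 112652561, fold 3.78). Dazl, which encodes an RNA-binding protein of germ cells, had one over its TSS on chromosome 17 (50293483 to 50293914, fold 3.44). The meiosis gene Meioc had an intronic peak 0.561 kb from the TSS on chromosome 11 (102666050 to 102666311, fold 3.37), and Mael one 1.16 kb from the TSS on chromosome 1 (166237446 to 166237662, fold 2.97, −log10 q of 0). Tdrd6 had a peak in the coding part of its first exon on chromosome 17 (43627586 to 43627998, fold 3.11), and Tdrd1 one in an intron on chromosome 19 (56846420 to 56847006, fold 3.44). Only the peak of Ddx4 had a q under 0.05.

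Among receptor families, vomeronasal receptor genes, which detect pheromones, were marked in 31 of 327 (9.48%, 95% interval 6.53 to 13.2%) against 2.27% of matched genes (permutation test, adjusted p = 0.00072, and 0.036 with rotation of the peaks). Their call was lost within 1 kb of the TSS, where 4 marked genes remained (1.22%, a ratio of 2.02 in place of 4.17, permutation test, adjusted p = 0.72), and their share fell to 3.67% with the stronger 50% of the peaks by −log10 p (permutation test, adjusted p = 0.011). Vmn1r81 (chromosome 7 from 12247291 to 12247645, fold 4.86) and Vmn1r65 (chromosome 7 from 6008079 to 6008395, fold 4.32) had the strongest peaks, both on the last exon, the former within its 3′ UTR. Olfactory receptor genes were marked in 24 of 1093 (2.20%) and showed no difference from matched genes that passed (1.35 times, permutation test, adjusted p = 0.33), although one did with the pooled list (3.48%, permutation test, adjusted p = 0.011) and with 5 kb added either side (4.67%, permutation test, adjusted p = 0.00060). With stricter peaks the direction turned, to 0.571 times matched genes in the stronger 50% (permutation test, adjusted p = 0.39) and 0.255 times with q under 0.05, chosen after seeing the data (permutation test, adjusted p = 0.064). Olfr843 on chromosome 9 (19248880 to 19249180, fold 3.69) and Olfr1349 on chromosome 7 (6515074 to 6515458, fold 3.52) led that list, both with a peak in coding sequence.

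UDP glucuronosyltransferase genes, enzymes that conjugate bilirubin and drugs, were marked in 9 of 21 (42.9%, 95% interval 21.8 to 66.0%) against 4.90% (permutation test, adjusted p = 0.00072, and 0.036 with rotation of the peaks). These 9 were one locus of nested Ugt1a genes with 8 peaks. Ugt1a1 and Ugt1a10 shared its strongest peak on chromosome 1 (88215457 to 88216367, fold 4.23, −log10 p 21.4), which included 308 bases of their common coding sequence. Only 1 of the 21 had a peak within 1 kb of the TSS, too few for a call although the ratio was 6.97 beside 8.74 over the gene body (permutation test, adjusted p = 0.72). Cytochrome P450 family 2 genes were marked in 6 of 48 (12.5%, 95% interval 4.73 to 25.2%) against 3.22% (permutation test, adjusted p = 0.025). That call was lost with rotation of the peaks (permutation test, adjusted p = 0.26), with the stronger 50% of the peaks by −log10 p (6.25%, permutation test, adjusted p = 0.25) and within 1 kb of the TSS, where no gene had a peak. The ratio to matched genes was 3.88 at first and 3.59 with the stronger 50%, where 3 marked genes remained. Under rotation, the share was 3.34 times that of the same genes with rotated peaks. Cyp2b13 on chromosome 7 (26083430 to 26083773) and Cyp2c29 on chromosome 19 (39302893 to 39303184) had intronic peaks, each of fold 3.78. The serpin list had 1 marked gene of 61, Serpinb6d (chromosome 13 from 33661590 to 33661810, fold 3.38). The beta-defensin list had 2 of 42, with Defb39 (chromosome 8 from 19060416 to 19060618, fold 2.83) the one seen in both replicates, and neither list passed against matched genes (permutation tests, adjusted p = 1 and 0.60). These counts depended on the peak list, with 3 serpin genes without replicate 1 and 2 without replicate 2, and no beta-defensin gene without replicate 2.

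The other 8 lists, 334 genes in all, held no gene with a replicated peak. None of the 40 hindbrain and neural progenitor genes, such as Sox2, Pax6 and Phox2b, overlapped one, and a limit of 3 genes on a count of 0 allows a share of up to 7.5% (exact 95% upper bound 8.81%). The same held for 39 Hox genes, which pattern the hindbrain along its length (up to 7.69%), 75 ribosomal protein genes (up to 4%) and 40 genes of liver, muscle, heart and skin (up to 7.5%). It also held for 30 blood, endothelial and mesenchymal marker genes (up to 10%), 24 genes of the H3K9 methylation machinery (up to 12.5%), 32 Rhox genes (up to 9.38%) and 54 keratin-associated protein genes (up to 5.56%). Matched genes carried peaks in 0.783 to 4.59% of cases, so none of these absences differed from matched genes (permutation tests, adjusted p from 0.89 to 1). A shortfall below those shares was not detectable with lists of this size. A large excess over separate loci was, as in the 44 imprinted genes, where 19 marked genes amounted to 15 loci. The 9 marked UDP glucuronosyltransferase genes were 1 locus, so they do not show this. Whether an excess would be seen in smaller lists of unlinked genes was not tested. Nor do the zeros hold in every peak list: of the 24 machinery genes, 1 had a peak in the pooled list and 2 without replicate 1. The replicates' own lists marked 16.7% and 29.2% of them, against 11.7% and 18.6% of all coding genes, which are not matched on length. In each replicate's unshared peaks alone, the machinery genes stood at the same 16.7% and 29.2%. Length-matched genes stood at 11.7% and 21.3% there (permutation tests, adjusted p = 0.78 and 0.69). The replicates' own lists marked 13.3% and 16.7% of the blood, endothelial and mesenchymal genes, and 0% and 7.5% of the neural progenitor genes. Those whole lists were not set against length-matched genes.

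**Figure D3:**
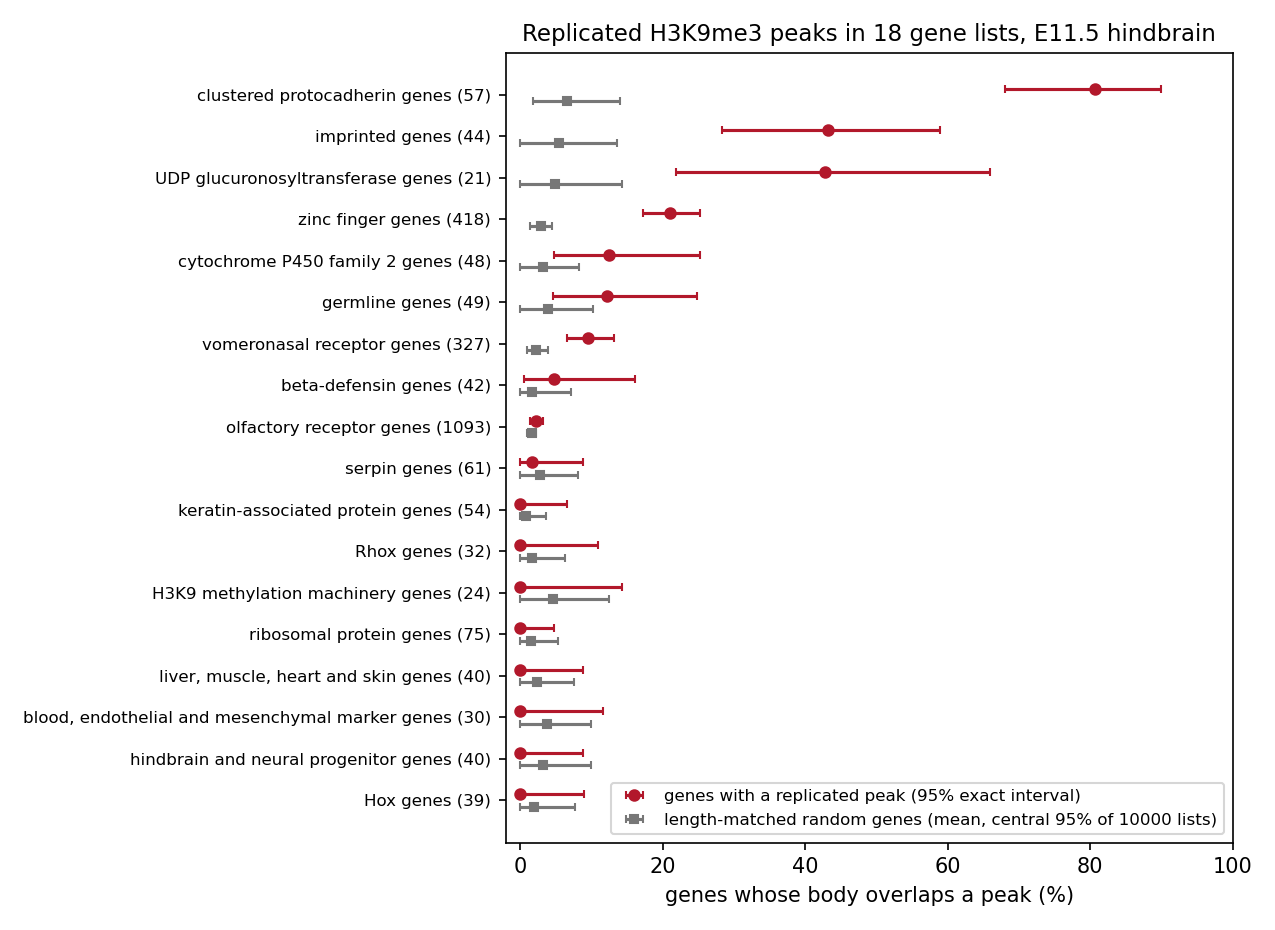
Percentage of genes whose body overlaps a replicated peak (horizontal axis) in each of 18 lists (number of genes in parentheses). Circles are the lists with exact 95% intervals, squares the mean of length-matched random lists with the central 95% of 10000 draws. Protocadherins stand at 80.7%, imprinted genes at 43.2% and zinc finger genes at 21.1%.

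Peaks were unevenly spread over the chromosomes. Chromosome 7 held 844 of the 4216 replicated peaks (20.0%), or 5.95 per Mb (95% interval 5.56 to 6.37), against 1.59 per Mb over all chromosomes. Chromosome 17 followed with 3.13 per Mb and chromosome 18 with 2.88. The X chromosome had 0.379 per Mb (0.291 to 0.486) and the Y chromosome 5 peaks in all. In each replicate's own list chromosome 7 was also the densest, with 14.9 per Mb in replicate 1 and 23.8 in replicate 2. X had 1.93 and 3.05 per Mb there, the lowest value of the chromosomes other than Y. Among autosomes, chromosomes 14 and 15 were also low in the replicated list, at 0.535 and 0.606 per Mb. With both sexes mixed in the pools, X and Y were present in fewer copies than autosomes. Whether that lowered their densities was not tested.

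**Figure D4:**
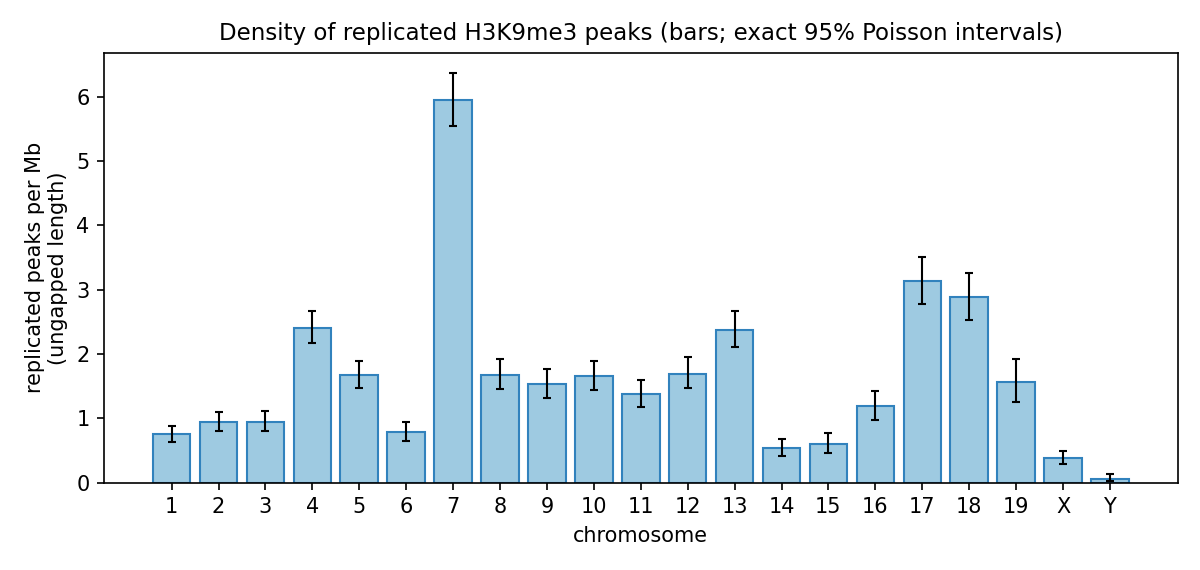
Replicated peaks per Mb of ungapped sequence (vertical axis, from 0) on each chromosome (horizontal axis). Error bars are exact 95% Poisson intervals. Chromosome 7 stands at 5.95 per Mb and X at 0.379 per Mb.

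Peaks gathered in a small number of regions. The densest 1 Mb window, chromosome 18 from 37 to 38 Mb, held 158 peaks, while the fullest window of any of 1000 random placements held 21 (permutation p = 0.001, the smallest these placements can give). In all, 38 windows exceeded 21 peaks, and together they held 38.9% of the replicated peaks. The genes with the strongest peak in the densest window were Gm37013, Gm37388 and Gm42416, gene models that run across the protocadherin cluster and share its peak of fold 5.67. The next window, chromosome 7 from 17 to 18 Mb, held 77 peaks. They included peaks in Ceacam14 (fold 4.73), Ceacam5 (fold 4.05) and Psg29 (fold 3.78), members of the carcinoembryonic antigen and pregnancy-specific glycoprotein families, but 18 of the 77 lay in coding genes. Chromosome 7 from 12 to 13 Mb held 75 peaks and 9 zinc finger genes, with Zfp606 (fold 5.94), Vmn1r81 (fold 4.86) and Zfp329 (fold 4.65) at their head.

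The 10 strongest replicated peaks on the chromosomes had folds between 6.75 and 9.92. Scaffold peaks were left out of this ranking, and 2 of them, with folds up to 7.98, would have entered it. Of these 10 chromosomal peaks, 7 lay within 1 Mb of the assembly gap that stands for the centromere. The strongest, on chromosome 18 from 3117851 to 3118468, had a fold of 9.92 from the pooled reads, 9.77 in replicate 1 and 10.1 in replicate 2, and the nearest TSS was that of Vmn1r238 at 5.28 kb. On chromosome 4, 4 peaks between 3049983 and 3084985 had folds from 7.02 to 8.55, with Vmn1r2 the nearest gene. On chromosome 16, 2 peaks (3231561 to 3233021, fold 7.97, and 3242775 to 3242989, fold 6.75) lay far from any coding gene, with Olfr161 the nearest. Away from centromeres, the peak over Klf14, an intronless gene of a Krüppel-like transcription factor, reached 8.10 (chromosome 6 from 30957064 to 30958764) and covered coding sequence and 659 bases of the 3′ UTR. A peak 14.5 kb upstream of Smok2a, a sperm motility kinase gene, reached 7.12 (chromosome 17 from 13206459 to 13207206). The remaining one was the peak on Zfp810, with a fold of 7.02.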

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

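Both tests of peaks on scaffolds were chosen only after the result was seen. The comparisons above used chromosomes alone, and 236 of the 4452 replicated peaks (5.30%) lay on unplaced or unlocalized scaffolds, where a count of 0 would allow 3. Replicate 1's own list had 277 such peaks and replicate 2's 289. The scaffold JH584304 held 56 replicated peaks with a median fold of 3.10, and the highest −log10 p of the list (71.0). GL456393 held 45 with a median fold of 3.78. Scaffold peaks had a median −log10 p of 7.55 (95% bootstrap interval 6.87 to 8.14) against 4.67 on chromosomes, and 23 of the 50 peaks with the highest −log10 p were on scaffolds. Those 23 had a median fold of 3.88 and the others, on chromosomes, one of 4.23. Over all scaffold peaks the median fold was 3.37 (3.24 to 3.56) against 3.32 on chromosomes. If the assembly holds fewer copies of these sequences than the genome does, reads would pile up in ChIP and control alike, giving a high −log10 p at an ordinary fold. If the mark were stronger there, the fold would be higher. With the interval reaching both sides of the chromosomal median, the 2 explanations cannot be told apart, because the lists hold no read counts for ChIP and control.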

How the results depend on the processing

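Of 253 recomputed values over 31 results and 22 settings, 209 kept their direction and their side of the threshold or stayed within their interval. These results include the 8 lists with no marked gene, and a share that stayed at 0 counts among the 209. That count is therefore not a measure of how firm the called results are. Another 22 turned direction, 18 of them in lists with no call before or after. The zinc finger, imprinted, protocadherin, vomeronasal and UDP glucuronosyltransferase lists kept their calls with the pooled list, with stricter peaks and under both nulls. They also kept them with the strongest peaks of either replicate's own list, the setting called without one replicate. Where these lists lost their calls, it was only through the gene window. Within 1 kb of the TSS, 3 lists passed in place of 6: shares were 1.20% for zinc finger, 1.22% for vomeronasal, 4.76% for UDP glucuronosyltransferase, 6.12% for germline (now called) and 0% for cytochrome P450 genes. On a gene's own first exon, chosen after seeing the data, 3 passed: 0.478%, 0.306%, 4.76%, 6.12% (called) and 0% in the same order. Those windows leave out most of the gene by construction. Olfactory receptor genes passed with the pooled list (3.48%) and with 5 kb either side (4.67%), and germline genes with rotation (12.2%). Lists without a call turned direction as few genes came or went. Without one replicate, germline genes lay between 4.08% and 6.12%, machinery genes between 0% and 8.33%, serpins between 3.28% and 4.92% and beta-defensins between 0% and 4.76%. In the stronger 50%, olfactory receptors were at 0.549%, serpins at 1.64% and beta-defensins at 0%, and with q under 0.05 olfactory receptors were at 0.183% and beta-defensins at 0%. With 5 kb either side, neural progenitor genes rose to 5% and machinery genes to 8.33%. Within 1 kb of the TSS, machinery genes were at 4.17%, serpins at 1.64% and beta-defensins at 0%, and on the own first exon olfactory receptors were at 0.274%, serpins at 1.64% and beta-defensins at 0%. Cytochrome P450 genes lost their call with the stronger 50% of peaks (6.25%), with q under 0.05 (4.17%, chosen after seeing the data) and with rotation (12.5%). With those stricter peaks the ratios to matched genes were 3.59 and 3.29 in place of 3.88. Under rotation, the ratio to the same genes with rotated peaks was 3.34. The cause of these changes was not tested. The share of peaks outside genes was 49.1% in the pooled list and between 47.9% and 49.6% without one replicate, and in replicate 2's whole list it was 51.9% and above that of placements. Chromosome 7 held between 13.4% and 14.8% of peaks without one replicate and 17.9% in the stronger 50%, in place of 20.0%. The densest window held 94 peaks in the stronger 50%, a shorter list by construction. The replicates' correlation was 0.318 on −log10 p. In unique sequence, chosen after seeing the data, the masked share was 18.8% and no longer below that of placements. No paired analysis was possible because only 1 group was profiled. Unknown depth limits how far a missing peak can be read as a missing mark.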

Other observations

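Predictions for the overlap between replicates and for the masked share in unique sequence were written before those results were seen, although the placements in unique sequence were added after the files had been examined. The test of peaks on exons in unique sequence and the comparison of peaks off exons with all placements off exons were chosen after the result was seen, and so were the scans of gene families, gene types and centromeric regions. Among 234 families of at least 10 protein-coding genes that share a symbol stem and lie outside the 18 lists, 4 carried replicated peaks more often than length-matched genes, all of them tandem families. Secretoglobin genes (Scgb) were marked in 7 of 33 (21.2%, against 0.862% of matched genes), all of the androgen-binding protein cluster on chromosome 7, such as Scgb1b24 and Scgb2b24. Ceacam genes, cell adhesion molecules, were marked in 6 of 15 (40%), and Nlrp genes, several of which act in the oocyte, in 7 of 17 (41.2%), with Nlrp4b, Nlrp4e and Nlrp5 among them and all on chromosome 7. Natural killer cell receptor genes (Klra) on chromosome 6 were marked in 4 of 11 (36.4%). Adjusted p was 0.016 for the first 3 families and 0.023 for Klra (permutation tests over 234 families). Genes of these families are neighbours, and the random lists do not keep that. Skint genes were marked in 4 of 11 and Sult genes in 4 of 21, without passing (permutation tests, adjusted p = 0.51 for each).

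Immunoglobulin heavy chain variable genes span chromosome 12 from 113578504 to 116000461, and that span held 75 replicated peaks, or 30.97 per Mb. Of its 113 variable genes, 5 overlapped a peak. No T cell receptor variable gene of 144 did. The first 1 Mb after the centromeric gap held 241 replicated peaks over 20 chromosomes, or 12.05 per Mb (95% interval 10.58 to 13.7), against 1.56 per Mb elsewhere. The excess was uneven, with 49 peaks on chromosome 3, 48 on chromosome 16 and none on chromosomes 1, 13, 14 and X. Replicate 1's own list had 24.75 per Mb there and 5.13 elsewhere, and replicate 2's 35.5 and 8.84. Several of the 10 peaks with the highest −log10 p lay in this part of chromosome 11, between 3184213 and 3200097. Their −log10 p ran from 48.0 to 65.5 at folds of only 2.81 to 3.41. Whether the assembly holds fewer copies of sequence beside the gaps than the genome does, as raised for the scaffolds, was not tested.

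H3K9me3 is known for repeats, yet replicated peaks held fewer repeat-masked bases than random placements. One candidate explanation is that reads from near-identical repeats cannot be placed. At least 90% of 31-mers were unique in 87.4% of the peaks and in 68.9% of random placements, and within that subset placements averaged 18.8% masked bases and peaks 18.8% (95% bootstrap interval 18.1 to 19.3%), which fits that explanation for the average. It does not account for peaks on exons in unique sequence, which averaged 10.99% (9.97 to 12.1%) against 13.7% of such placements (13.02 to 14.9% over draws). All replicated peaks, without that filter, averaged 21.4%. The frequency of exons was to be tested in unique sequence, where peaks that overlap no exon averaged 20.6% (19.9 to 21.3%) and placements that overlap none 19.4%. Peaks off exons there lay above the highest draw of placements (19.7%), so the equal averages hide opposite differences on and off exons. With no deficit left off exons, that test could not decide. Over all sequence, peaks that overlap no exon averaged 23.5% masked bases (22.7 to 24.3%) and placements that overlap none 35.9%, which counts against exons as the whole cause and leaves a part open. No biological explanation was tested.

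A minority of each replicate's peaks overlapped the other's. If only peaks near the calling threshold differed, the strongest 10% of replicate 1's peaks would have been overlapped at a share of 80% or more. It was 67.1% (95% interval 64.5 to 69.6%), above the 19.5% of the weakest 10%. The strongest 10% of replicate 2's longer list were overlapped at 48.6% (46.5 to 50.7%), at the bound of 50% set for replicate 1 as counting against this explanation. With that interval on both sides of the bound, weak peaks remain a candidate cause of part of the difference and the rest stays open. With both lists cut to q under 0.01, replicate 1's share fell from 31.7% to 25.4% and replicate 2's rose from 18.8% to 23.6%. That cut also removes possible partners, so it does not decide. If the 2 embryo pools were marked in different places, some lists raised in one replicate's unshared peaks would be at or below matched genes in the other's. Of 7 lists at 2 times matched genes or more in the unshared peaks of either replicate, 0 were at or below matched genes in the other. Zinc finger genes, for example, were at 3.36 times in the 9234 unshared peaks of replicate 1 and at 2.35 times in the 18801 of replicate 2. UDP glucuronosyltransferase genes were called in those of replicate 1 alone, at 3.02 times (permutation test, adjusted p = 0.010) against 1.48 times in replicate 2 (permutation test, adjusted p = 0.54). That test covers the direction in gene lists, not its size and not single positions, and the unknown depth of each library was not tested.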
